A study of Tribolium castaneum with 27 samples.

How the data were processed

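Messenger RNA levels were measured by paired-end RNA sequencing of pooled eggs of the red flour beetle Tribolium castaneum. Per the labels there were 3 egg types: wildtype eggs, eggs of mothers injected with a double-stranded RNA (dsRNA) of no Tribolium gene (control), and eggs of mothers injected with dsRNA against Tc-zen1, which form no serosa (zen1). Each type was left untreated (naive), pricked with a clean needle (sterile) or pricked with a needle carrying the bacteria Escherichia coli and Micrococcus luteus (septic). With 3 replicates this gave 9 groups and 27 libraries. The labels state the extraction with TRIzol and an RNeasy column after removal of the chorion, but not the age of the eggs or the time from prick to extraction.

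The deposited files hold 1 table per library with 16541 features. Per the file headers, the values used here are the count of reads in the exons of a gene, which the files call total exon reads. They are whole numbers whose totals differ between libraries, so no scaling had been applied. The files' RPKM column was not used. The features are named after an official gene set of the species, with linkage groups X and 2 to 10 as chromosomes. Aligner, counting software and genome build are not given in the sources used here, so coordinates are those of the files. A symbol was given for 1438 features, and 15103 had only a number. The reference held the gene table of a newer assembly, in which 458 of the symbols and 1 of the numbered features were found. No gene descriptions were available, so what a numbered gene encodes is not stated.

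Libraries held 2.36 to 11.66 M (1e6) exon reads, with a median of 4.16 M. Between 98.05% and 98.62% of them mapped to 1 place. Replicates numbered 3 were deeper, with a median of 8.35 M against 3.87 and 3.51 M for those numbered 1 and 2. No library duplicated another, as checked by comparing all pairs within a group with counting noise. Intervals around read totals are exact Poisson intervals at 95%. These intervals, and the upper limit of 3 reads set beside a count of 0, cover counting error only, because reads without molecular identifiers are not independent molecules.

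Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the groups with its minimum count of 10, which left 9415. After TMM scaling, 1 quasi-likelihood model with a mean per group was fitted to all libraries. Its common biological coefficient of variation was 0.0956. The 16 comparisons were contrasts of that model. Among them, 4 compare a response (pricked minus naive) between egg types as an interaction. P values were adjusted by Benjamini-Hochberg over all genes of a comparison and called at an adjusted p under 0.05. Fold changes are given as log2 values. Their standard errors (SE) are approximate, computed as the size of the log2 fold change divided by the square root of the test's F statistic. Levels are counts per 1e6 reads (CPM) after that scaling, as mean ± SD of 3 libraries. Where every library of the lower group was at 0, the change is given as a bound against a floor of 3 reads over that group. The labels do not say whether replicates came from separate parents or cultures, so the p values measure the spread between these samples. Replicate numbers are not stated to pair samples and were used as a block only as an alternative.

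The tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took genes with a symbol, an adjusted p under 0.05, at least 5 CPM in the higher group and all 3 libraries of that group above all 3 of the other. Of these, the 10 with the highest and the 10 with the lowest log2 fold change could be named in 3 lead comparisons (septic against naive control eggs, zen1 against control naive eggs, and their difference in septic response) and 3 each way in the others, with up to 4 members of each gene list by smallest p. The text names fewer, in that order. In the interactions the separation had to hold for septic against naive eggs in the type with the larger response. ZEN, taken as the gene targeted by the dsRNA, is always given. It was filtered out for low counts, so its test comes from the same model fitted without the filter. A symbol used by several features is followed by its start position. Gene lists fixed at that stage were to be matched to names and descriptions. Because descriptions were missing, 27 lists of symbols were written after the feature names, but not their values, had been seen. In those lists, P and H followed by a number were read as serine proteases and serine protease homologs of the numbered Tribolium immune gene set.

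Of these lists, 25 with at least 3 tested members were compared with all other genes by camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. P values were adjusted over the lists within a comparison. The test was repeated with a correlation estimated from the data, and a list's call is given with that p wherever it was lost. Counts of called members are given over all genes tested and adjusted over the list alone.

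The procedure was tested on simulated data with the dispersions of these libraries. Simulated genes and libraries varied independently, and each gene had the same dispersion in all groups. The shares that follow therefore do not cover libraries alike by replicate number or groups of unequal spread. In the septic against naive comparison of control eggs it recovered 46.3% of genes changed 1.5-fold, 73.1% of genes changed 2-fold and 95.5% of genes changed 4-fold, with 5.3% of calls false. For the difference in septic response between zen1 and control eggs the shares were 28.4%, 55.2% and 90.9%, with 3.33% false. The alternatives were another scaling (RLE), no count filter, replicate number as a block, DESeq2 1.42.0, only the libraries of the compared groups, an adjusted p under 0.01 with at least a 2-fold change, and leaving out each library in turn. Reads mapping to 1 place in place of all exon reads were added after the files were seen.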

Results

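Messenger RNA of whole eggs was sequenced in 9 groups of 3 libraries, formed by 3 egg types (wildtype, control dsRNA and zen1 dsRNA) and 3 treatments (naive, sterile prick and septic prick). The zen1 eggs lack the serosa, an epithelium outside the embryo that encloses embryo and yolk. The design asks whether that epithelium carries the egg's response to bacteria. In replicate order, wildtype libraries held 5.54, 3.66 and 10.23 M (1e6) exon reads when naive, 3.37, 3.2 and 11.66 M after a sterile prick, and 3.77, 4.59 and 9.52 M after a septic prick. Control libraries held 4.32, 3.49 and 9.52 M, 4.16, 3.56 and 6.64 M, and 3.1, 3.51 and 6.04 M in the same order. Those of zen1 eggs held 3.87, 2.36 and 7.17 M, 4.99, 3.6 and 8.35 M, and 3.27, 2.97 and 8.05 M. Between 10880 and 12282 genes had reads in a library. The 9 zen1 libraries lay apart from all others on the first dimension of a multidimensional scaling plot. On the second dimension, the wildtype and control libraries lay lowest when naive, higher after a sterile and highest after a septic prick. Libraries with the same replicate number were more alike than others: 19 of 27 deviated from their group most like a library with their own number. Each number holds 1 library per group, so counts are also given with that number as a block.

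**Figure D1:**
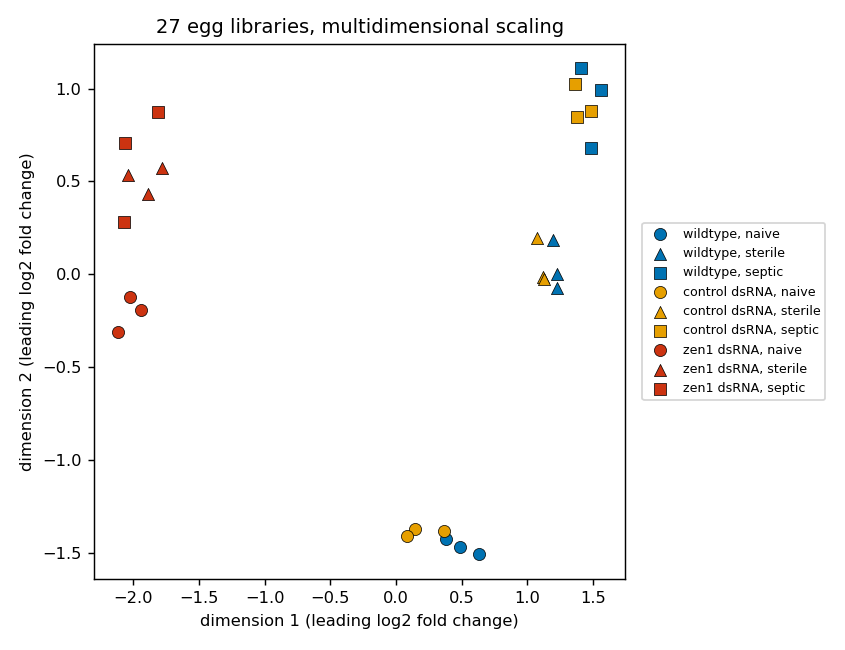
Multidimensional scaling of the 27 libraries, with the leading log2 fold change between libraries on both axes, egg type by colour and treatment by symbol. The zen1 libraries lie between -2.11 and -1.78 on dimension 1, and all libraries of the other egg types lie above 0.

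ZEN was taken as the gene targeted by the dsRNA, zen1, a match assumed from the symbol, as the files give ZEN no number. ZEN, on linkage group 2 (10319914 to 10320762), was scarce, with 6 reads in the 44.64 M exon reads of the 9 zen1 libraries, or 0.134 reads per M (95% interval 0.0493 to 0.293). Control eggs had 51 reads in 44.35 M, or 1.15 per M (0.856 to 1.51), and wildtype eggs had 33 in 55.55 M, or 0.594 per M (0.409 to 0.834). Single libraries held 0 to 2 reads in zen1 eggs, 2 to 10 in control eggs and 0 to 7 in wildtype eggs. At this depth the log2 difference from control eggs was -3.39 ± 1.14 (SE) in naive eggs (adjusted p = 0.0835), -2.41 after a sterile prick (adjusted p = 0.147) and -3.34 after a septic prick (adjusted p = 0.0257). Only the septic difference passed, in edgeR over all genes, and it missed the threshold without control septic 1 (-3.07, adjusted p = 0.105), control septic 2 (-3.28, 0.0648), zen1 septic 1 (-2.99, 0.0842) or zen1 septic 3 (-3.16, 0.2). Against wildtype eggs the differences were -2.58, -1.26 and -2.68 in naive, sterile and septic eggs (adjusted p = 0.338, 0.675 and 0.144). Without zen1 naive 3 the naive differences were -5.35 from control and -4.55 from wildtype eggs, and without zen1 sterile 3 the sterile ones were -1.56 and -0.404. The sterile difference from wildtype eggs was also -0.776, -0.319 and -2.43 without wildtype sterile 1, 2 and 3, and -2.16 without zen1 sterile 1. The neighbouring ZEN2 (10321045 to 10322024) had 176 reads in zen1, 861 in control and 1199 in wildtype eggs. It was lower in zen1 eggs in all 6 such tests, by log2 values from -2.80 to -1.77, with adjusted p at most 1.35e-07.

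Comparing naive zen1 with naive control eggs asks what the missing serosa takes out of the egg. A few transcripts that were among the most abundant in control eggs nearly disappeared. CSP20, a member of the chemosensory protein family, fell from 6710 ± 879 to 18.9 ± 5.34 CPM (mean ± SD, n = 3; log2 fold change -8.38 ± 0.311, edgeR adjusted p = 1.04e-17). The numbered genes TCOGS2:TC002718 (linkage group 3, 16465501 to 16465965) and TCOGS2:TC008888 (linkage group 7, 14511092 to 14511586) fell from 6730 ± 599 to 2.41 ± 2.7 CPM and from 4390 ± 1200 to 1.67 ± 0.832 CPM. The protease P61 fell from 15.2 to 0.133 CPM, the lipid recognition protein ML5 from 125 to 2.23 CPM and the chemosensory protein CSP14 from 63.6 to 1.43 CPM. P53, a symbol used both for a tumour suppressor and for a numbered protease, fell from 202 ± 19.5 to 5.1 ± 0.689 CPM. The odorant-binding protein OBP-C12 was the highest riser with a symbol, from 5.01 ± 3.11 to 37.7 ± 18.6 CPM (log2 fold change 3.18 ± 0.39, adjusted p = 8.93e-07).

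Components of the extracellular protease cascades were lower as a group in naive zen1 eggs. Of 38 serine proteases 15 fell and none rose (16 and 4 adjusted over the list alone), and the list moved down against all other genes (camera adjusted p = 5.04e-06), with P44 at -2.81 and P141 at -3.46. The homologs, which are related to these proteases but lack their activity, had 8 of 24 lower and 1 higher (10 and 1 adjusted over the list alone; camera adjusted p = 2.61e-05), among them H78 at -4.79 and H18 at -3.24. Among 20 serpins, the inhibitors of such proteases, 6 fell and 2 rose (10 and 3 adjusted over the list alone; camera adjusted p = 0.000495). SERPIN1 fell from 636 ± 49.7 to 143 ± 6.05 CPM, whereas SERPIN24 rose from 27.7 to 48.8 CPM. Of 11 chitin-binding cuticle proteins 5 fell and none rose (6 and 0 adjusted over the list alone; camera adjusted p = 2.07e-05), including CPAP3-A1 (162 to 32.8 CPM) and OBST-B (92.5 to 20.4 CPM). All 4 lists kept an adjusted p under 0.05 with an estimated correlation. By contrast, no gene was called, over all genes or adjusted over the list alone, among 11 genes of the IMD pathway, 7 of yolk and fat body, 25 of segmentation, 8 of mesoderm, 6 of the germ line, 15 of the cell cycle or 23 of mitochondrial respiration. The Toll pathway list had 1 lower gene of 13, SPZ4 at -1.16 (the same adjusted over the list alone). Of 8 Hox genes PB was lower at -0.98 (3 lower and 1 higher adjusted over the list alone).

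Over all 9415 genes, 656 were called between naive zen1 and control eggs, 203 higher and 453 lower, of which 46 and 257 changed at least 2-fold; a block on replicate number gave 802. Against wildtype eggs 611 were called, 163 higher and 448 lower (751 with the block). There CSP20 fell from 5690 ± 1050 CPM (log2 fold change -8.15), P61 was at -8.42, ML5 at -6.34 and OBP-C12 at 2.57. The 4 lists moved down again: 15 of 38 proteases fell and 1 rose (19 and 4 adjusted over the list alone; camera adjusted p = 7.39e-09), and 7 serpins fell and 1 rose (9 and 1 adjusted over the list alone; adjusted p = 9.9e-05). Each gene named as called between 2 groups, here and in what follows, had all 3 libraries of the higher group above all 3 of the lower; chance gives such a split to 10% of genes. Neuronal genes were called up as a list against wildtype (adjusted p = 0.00156), with 1 higher gene of 31 and adjusted p = 0.474 with an estimated correlation. The list of lipid recognition proteins, where ML5 was the called gene of 3, had adjusted p = 0.0307, and adjusted p = 0.0722 with an estimated correlation.

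Control against wildtype naive eggs asks what injecting the mothers does. It gave 423 called genes, 259 higher and 164 lower in control eggs (563 with the block). The chitinase CHT5 had 6.11 ± 5.51 CPM in wildtype and 32.9 ± 13 CPM in control eggs (log2 fold change 2.17 ± 0.588, adjusted p = 0.0334), and TCKR-H1 had 3.55 ± 4.8 and 20.1 ± 3.35 CPM. Of 31 genes of the nervous system 6 rose (18 and none lower adjusted over the list alone), such as the acetylcholine receptor subunit NACHRA6 at 1.04, with camera adjusted p = 1.47e-07 but adjusted p = 0.296 with an estimated correlation. Cell cycle genes were called down as a list (adjusted p = 0.000647; adjusted p = 0.296 with an estimated correlation), with 1 of 15 called. The count of this comparison depended on which library was left out. It was 2, 1 and 1195 without wildtype naive 1, 2 and 3, and 2, 6 and 640 without control naive 1, 2 and 3. It thus fell without replicate 1 or 2 of either type and rose without replicate 3 of either. On the first dimension of the scaling plot, wildtype naive 1, 2 and 3 lay at 0.486, 0.631 and 0.384. Control naive 1, 2 and 3 lay at 0.144, 0.0815 and 0.365, so the types lay closest in replicate 3. Fitted with only the libraries of its 2 groups, it called 0 genes. CHT5 and TCKR-H1 lost their calls without wildtype naive 1 (adjusted p = 0.176 and 0.128), wildtype naive 2 (0.19 and 0.155), control naive 1 (0.0884 and 0.0793) or control naive 2 (0.177 and 0.128), and had log2 fold changes of 3.39 and 4.81 without wildtype naive 3. NACHRA6 lost its call without the same 4 libraries (adjusted p = 0.112, 0.147, 0.075 and 0.117).

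Septic against naive control eggs asks what an egg with a serosa does after a prick that brings in bacteria. Named genes of recognition, signalling, protease cascades and antimicrobial defence were among those that rose. The protease P8 rose from 5.1 ± 0.466 to 206 ± 19 CPM (n = 3; log2 fold change 5.29 ± 0.216, edgeR adjusted p = 1.62e-16). The homolog H70 rose from 0.614 ± 0.199 to 36.8 ± 3.8 CPM (5.73), the protease P83 from 0.363 to 16.2 CPM (5.29) and the antimicrobial peptide gene CEC3, a cecropin, from 0.109 ± 0.112 to 5.35 ± 0.791 CPM (5.28). SPZ-LIKE, named after the ligand of the Toll receptor, rose from 1.09 ± 0.594 to 46.7 ± 4.55 CPM (5.17), and the serpin SERPIN26 from 20.6 ± 0.627 to 373 ± 87.5 CPM (4.18). SNMP02, OBP12 and the heat shock gene HSP68B at 6605773 on linkage group 7 rose by 4.95, 4.22 and 4.25. Genes that fell changed less, with CYP9Z1, a cytochrome P450, at -1.88 ± 0.376 (8.04 to 2.16 CPM) and NIMA, on the list of phagocytosis receptors, at -1.67 ± 0.306 (19.5 to 6.19 CPM).

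The lists for immunity responded unevenly in septic control eggs. Of 38 proteases 21 rose and 2 fell (22 and 4 adjusted over the list alone; median log2 fold change 0.93; camera adjusted p = 2.92e-10, and 6.74e-06 with an estimated correlation), with P93 rising from 51.9 ± 2.33 to 367 ± 40.7 CPM and P10 from 8.65 to 114 CPM. Among 20 serpins 9 rose and 3 fell (10 and 3 adjusted over the list alone; adjusted p = 7.14e-06, and 0.00813 with an estimated correlation), with SERPIN24 rising from 27.7 ± 2.53 to 382 ± 42.8 CPM. Both recognition proteins tested rose, GNBP3 from 9.5 to 53.1 CPM and GNBP2 from 7.85 to 39.6 CPM. In the IMD pathway 2 of 11 genes rose (2 and none lower adjusted over the list alone; adjusted p = 0.346): the adaptor IMD from 15.6 ± 2.68 to 53.1 ± 3.88 CPM and the NF-kB factor REL from 239 ± 9.68 to 569 ± 65.2 CPM (log2 fold change 1.25 ± 0.104, adjusted p = 3.47e-10). In the Toll pathway 4 of 13 rose and 2 fell (4 and 2 adjusted over the list alone; adjusted p = 0.397), with the transcription factor DL at 0.33 and SPZ4 at -0.99. Of 8 genes of the JNK pathway and wounding 2 rose (2 and none lower adjusted over the list alone; adjusted p = 0.134): the matrix metalloproteinase MMP1 from 6.28 ± 1.43 to 52.6 ± 1.73 CPM and KAY, the Fos subunit of AP-1, at 0.62. The homologs had 8 of 24 higher and 4 lower (9 and 4 adjusted over the list alone; adjusted p = 0.0541), with H4 at 3.87. None of the 3 genes of the JAK/STAT pathway was called.

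Heat shock, cytochrome P450 and segmentation genes were also among those called in septic control eggs. The heat shock list holds the neighbouring HSP68B features at 6605773 and 6609828 and the J-domain chaperones DNAJ2 and DNAJ3. Of these 4 genes 3 rose (3 and none lower adjusted over the list alone, with camera adjusted p = 0.0332, and adjusted p = 0.229 with an estimated correlation). Of 39 cytochrome P450 genes 3 rose and 6 fell (3 and 7 adjusted over the list alone; adjusted p = 0.54), CYP6BK13 at 2.20 and CYP346A2 at -1.12. The segmentation genes FTZ and GSB rose by 0.61 and 0.60 and were among 4 of 25 called (4 and none lower adjusted over the list alone; adjusted p = 0.353). HR38, a nuclear receptor, rose by 2.09. No gene was called on the lists for chitin synthesis (3 genes), chitin-binding proteins (11), serosa and amnion patterning (9), yolk and fat body (7) and germ line (6). Over all genes 1506 were called, 955 higher and 551 lower, and 410 and 152 of them changed at least 2-fold; with the block 1731 were called.

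Wildtype septic eggs gave 1802 called genes, 1032 higher and 770 lower (2134 with the block). They shared 654 higher and 297 lower genes with control septic eggs, where 105 and 45.1 would be shared by chance. H70 rose from 0.0615 to 30.7 ± 5.79 CPM (log2 fold change 8.65 ± 0.513, adjusted p = 3.78e-13). CEC3 had no read in the naive libraries and was at least 38.6-fold higher after the prick, against a floor of 3 reads over the group; CSP07 was at least 32.5-fold higher. P8 rose by 4.92, SPZ-LIKE by 5.89, GNBP3 by 2.36, IMD by 1.72, REL by 1.07 and MMP1 by 3.49. The esterase EST-6 fell from 103 ± 18.9 to 30.5 ± 7.32 CPM, and the cytochrome P450 genes CYP9AA1 and CYP4Q8 fell by 2.46 and 1.57. Proteases (20 higher, 5 lower of 38; 22 and 7 adjusted over the list alone; camera adjusted p = 2.66e-07) and serpins (9 higher, 3 lower of 20; 10 and 3 adjusted over the list alone; 3.41e-05) kept their calls with an estimated correlation. Lists for the JNK pathway and wounding (camera adjusted p = 0.0255), heat shock (0.0243) and the nervous system (0.0174) lost theirs, with adjusted p = 0.127, 0.19 and 0.518 with an estimated correlation.

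The sterile prick separates the wound from the bacteria. Several of the genes that rose after the septic prick also rose with the wound alone. In control eggs P83 rose from 0.363 to 20.5 ± 4.22 CPM (log2 fold change 5.63), H70 from 0.614 to 13.3 CPM, P8 from 5.1 to 54.3 ± 10 CPM and SERPIN24 from 27.7 to 246 ± 26.9 CPM. GNBP3 rose by 2.12, MMP1 by 2.68, CEC3 by 4.09, SPZ-LIKE by 3.38 and IMD by 0.86. REL was an exception, with 239 ± 9.68 CPM in naive and 255 ± 8.46 CPM in sterile control eggs (0.09, adjusted p = 0.669). Wildtype eggs had H70 at 7.69, P83 at 4.44, SERPIN30 at 3.09, GNBP3 at 2.18, MMP1 at 2.94 and IMD at 1.01 after the sterile prick. CEC3 was at least 21-fold higher there, and REL was at 0.07 (adjusted p = 0.765).

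Of 38 proteases 18 rose and 1 fell after the sterile prick in control eggs (19 and 2 adjusted over the list alone; camera adjusted p = 2.84e-11) and likewise 18 and 1 in wildtype eggs (19 and 2 adjusted over the list alone; 6.96e-09). Serpins had 9 higher and 1 lower of 20 in control eggs (9 and 3 adjusted over the list alone; adjusted p = 4.12e-06) and 8 and 3 in wildtype eggs (11 and 4 adjusted over the list alone; 3.36e-06). The homologs were called up as a list in control and wildtype eggs (adjusted p = 0.0177 and 0.0258), as was the list of chemosensory receptors and binding proteins (0.00761 and 0.0098). These held with an estimated correlation, unlike heat shock genes in control eggs (adjusted p = 0.0177; adjusted p = 0.256 with an estimated correlation) and neuronal genes in wildtype eggs, called up with no called member (0.0249; adjusted p = 0.498 with an estimated correlation). In all, 816 genes were called in control eggs (585 higher, 231 lower; 989 with the block) and 776 in wildtype eggs (479 higher, 297 lower; 936 with the block). The types shared 362 higher and 109 lower genes, where chance gives 29.8 and 7.29. The wildtype count was 512 without wildtype sterile 2.

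Septic against sterile eggs isolates what the bacteria add to the wound. In eggs with a serosa REL rose with the bacteria, from 255 ± 8.46 to 569 ± 65.2 CPM in control eggs (log2 fold change 1.16, adjusted p = 1.59e-08) and from 262 ± 21.7 to 520 ± 91.1 CPM in wildtype eggs (0.99, adjusted p = 2.08e-07). P8 rose further by 1.94 and 1.82, SPZ-LIKE by 1.80 and 2.56, P93 by 1.27 and 1.14, and SERPIN26 by 1.24 and 1.20 in control and wildtype eggs. IMD rose by 0.94 and 0.71, the latter lost without wildtype sterile 3 (0.65, adjusted p = 0.087). HR38 rose by 1.60 and 1.67. FPPS, a farnesyl pyrophosphate synthase, fell from 109 to 73.5 CPM in control and from 114 to 68.3 CPM in wildtype eggs. Of 38 proteases 5 rose and 1 fell in control eggs (8 and 2 adjusted over the list alone; camera adjusted p = 0.00681, and 0.0189 with an estimated correlation). In wildtype eggs 7 rose and 2 fell (11 and 2 adjusted over the list alone; adjusted p = 0.0291, and adjusted p = 0.0706 with an estimated correlation). Serpins had 3 higher and 1 lower of 20 in control eggs (4 and 1 adjusted over the list alone; adjusted p = 0.00284) and 4 higher in wildtype eggs (4 and 1 adjusted over the list alone; 0.0291), with adjusted p = 0.0656 and 0.205 with an estimated correlation. Heat shock genes had no called member in wildtype eggs (3 higher adjusted over the list alone), with camera adjusted p = 0.0291 and adjusted p = 0.255 with an estimated correlation.

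The bacteria changed 124 genes in control eggs (94 higher, 30 lower; 144 with the block) and 155 in wildtype eggs (123 higher, 32 lower; 191 with the block), with 80 higher and 17 lower genes in common against 1.23 and 0.102 by chance. The wildtype count was 102 without wildtype sterile 1, 87 without sterile 3, and 101, 92 and 248 without septic 1, 2 and 3. In zen1 eggs 2 genes were called, both higher, with 384 at an unadjusted p under 0.05. DESeq2 and the block also gave 2, no count filter gave 3, and fitting only the compared groups gave 0. They carry numbers only and are named here because the count is small. TCOGS2:TC013620 (linkage group X, 3998517 to 3999223) had 1.45 ± 1.2 CPM after a sterile and 26.3 ± 19.7 CPM after a septic prick (log2 fold change 3.73 ± 0.631, adjusted p = 0.0383). GLEAN_07737 (linkage group 4, 100352 to 100901) had 8.51 ± 3.53 and 94.1 ± 68.9 CPM (3.25 ± 0.587, adjusted p = 0.0388). Both missed the threshold without zen1 sterile 1, 2 or 3 or zen1 septic 1 or 2, with adjusted p from 0.098 to 0.502 and a count of 0 each time. In control eggs, looked up after these values were seen, GLEAN_07737 rose from 20.5 to 1351 CPM (6.11 ± 0.532, adjusted p = 1.05e-08) and TCOGS2:TC013620 from 9.59 to 126 CPM (3.75). No list was called in zen1 eggs.

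**Figure D2:**
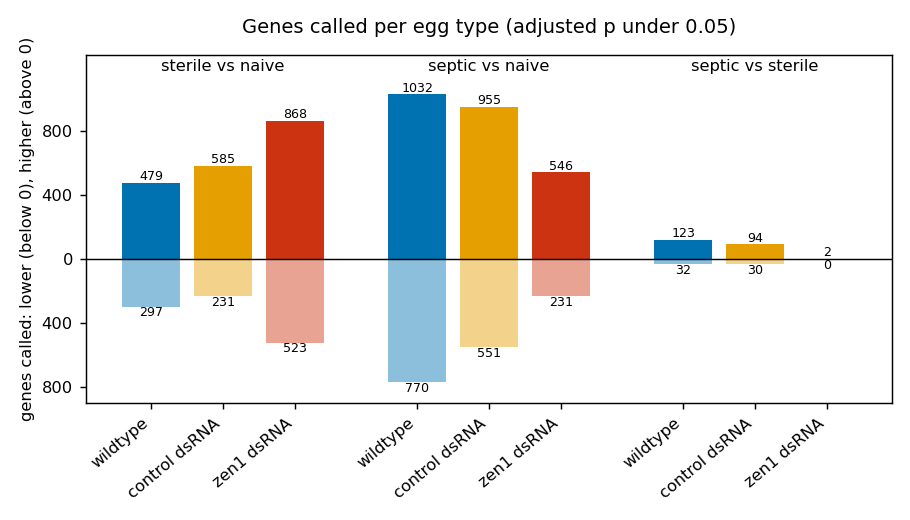
Number of genes called higher or lower (adjusted p under 0.05, y axis) in each egg type for septic against naive, sterile against naive and septic against sterile eggs. Bacteria changed 155 genes in wildtype, 124 in control and 2 in zen1 eggs relative to the sterile prick.

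Eggs without a serosa also changed many genes after pricking. After a sterile prick BMP10, named after a growth factor, rose from 0.804 ± 0.356 to 8.68 ± 1.99 CPM (log2 fold change 3.23), the trehalase TREH-1 from 0.557 to 5.99 CPM (3.18) and HSP68B at 6605773 from 6.34 ± 1.56 to 31 ± 13.3 CPM (2.26). CYP4Q8 fell from 24.1 ± 3.71 to 6.14 ± 0.885 CPM (-1.98), the esterase EST2 was at -1.77 and CYP346A2 at -1.62. Of 39 cytochrome P450 genes 3 rose and 12 fell (4 and 12 adjusted over the list alone; camera adjusted p = 0.0149, and adjusted p = 0.347 with an estimated correlation). Segmentation genes had 4 of 25 higher (5 and none lower adjusted over the list alone; adjusted p = 0.0307, and adjusted p = 0.871 with an estimated correlation), with FTZ rising from 42.8 ± 3.22 to 78.5 ± 2.6 CPM. Heat shock genes had 3 of 4 higher (4 and none lower adjusted over the list alone; adjusted p = 0.0149, and adjusted p = 0.347 with an estimated correlation). Proteases had 3 higher and 2 lower of 38 (3 and 2 adjusted over the list alone; camera adjusted p = 0.818), and 1 serpin rose while 4 fell (1 and 4 adjusted over the list alone; adjusted p = 0.71), SERPIN18 at -1.13 and SERPIN19 at -1.54. In total 1391 genes were called in sterile zen1 eggs, 868 higher and 523 lower (1623 with the block). The count was 847 without zen1 naive 1 and 831 without zen1 sterile 1.

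After the septic prick zen1 eggs had 777 called genes, 546 higher and 231 lower (994 with the block). FTZ rose from 42.8 ± 3.22 to 75.4 ± 6.22 CPM (log2 fold change 0.80 ± 0.104, adjusted p = 1.21e-05) and CNN, of the cell cycle list, from 353 ± 33.6 to 512 ± 66.1 CPM, while CYP4Q8 fell from 24.1 to 8.32 CPM. REL rose from 260 ± 16.1 to 360 ± 47.1 CPM (0.47 ± 0.104, adjusted p = 0.00568), a call lost without zen1 naive 1 (0.41, adjusted p = 0.058) or zen1 septic 1 (0.38, 0.0646). Sterile zen1 eggs already had REL at 338 ± 5.76 CPM, and REL was not called between septic and sterile zen1 eggs. The recognition genes GNBP2 and GNBP3 were at 0.29 and -0.02 (adjusted p = 0.523 and 0.971) and MMP1 at 0.34 (adjusted p = 0.26). KAY rose from 42.5 ± 0.923 to 64.2 ± 9.52 CPM (0.58 ± 0.146, adjusted p = 0.0123). CEC3 had 0 reads in all 9 zen1 libraries, which allows up to 0.0672 reads per M. Proteases had 1 higher and 2 lower of 38 (4 and 3 adjusted over the list alone; camera adjusted p = 0.637), serpins 3 higher and 3 lower of 20 (3 and 3 adjusted over the list alone; 0.953), the IMD pathway 4 higher and 1 lower of 11 (4 and 2 adjusted over the list alone; 0.953), and none of 13 Toll genes was called. Segmentation genes had 5 of 25 higher (6 and none lower adjusted over the list alone; adjusted p = 0.0394, and adjusted p = 0.815 with an estimated correlation). Heat shock genes had 3 of 4 higher (4 and none lower adjusted over the list alone, with camera adjusted p = 0.0172, and adjusted p = 0.643 with an estimated correlation). The called ones were the HSP68B features at 1.81 and 2.13 and DNAJ3 at 0.32. Called genes common to septic zen1 and control eggs numbered 291 higher and 102 lower, where chance gives 55.4 and 13.5. The zen1 count was 307 without zen1 naive 1, and 267 and 419 without zen1 septic 1 and 2.

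Whether the response to a septic prick differs without a serosa was tested as an interaction, septic minus naive in zen1 eggs against the same in control eggs. This response holds the wound as well as the bacteria. A later test of septic against sterile eggs, zen1 against control, called 32 genes. REL, P93 and SERPIN27 were among them, while SERPIN26 (edgeR adjusted p = 0.059) and IMD (0.0717) were not. Several of the strongest risers of control eggs changed little in zen1 eggs. P8 went from 1.14 ± 0.647 to 1.77 ± 0.569 CPM in zen1 eggs against 5.1 ± 0.466 to 206 ± 19 CPM in control eggs (difference in log2 response -4.92 ± 0.749, edgeR adjusted p = 8.11e-05). SERPIN26 went from 29.3 ± 8.12 to 38.9 ± 8.05 CPM in zen1 eggs (difference -3.86 ± 0.253, adjusted p = 4.97e-11), and P93 from 16.3 ± 0.637 to 17.2 ± 7.56 CPM (-2.88). P10, SERPIN24, MMP1 and SERPIN27 differed by -3.29, -3.15, -2.65 and -2.58. The recognition genes GNBP3 and GNBP2 differed by -2.50 and -2.16, the adaptor IMD by -1.97 ± 0.244 (adjusted p = 4.12e-06; 14.4 to 13.6 CPM in zen1 eggs) and REL by -0.79 ± 0.146 (adjusted p = 0.00116). P83 differed by -5.11 ± 1.08 (adjusted p = 0.00517), a call lost without zen1 naive 1 (-4.63, adjusted p = 0.0973) or zen1 naive 3 (-5.19, 0.0678). Large differences for H70 (-4.58, adjusted p = 0.121) and SPZ-LIKE (-4.08, adjusted p = 0.422), whose zen1 levels were near 0, did not pass.

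**Figure D3:**
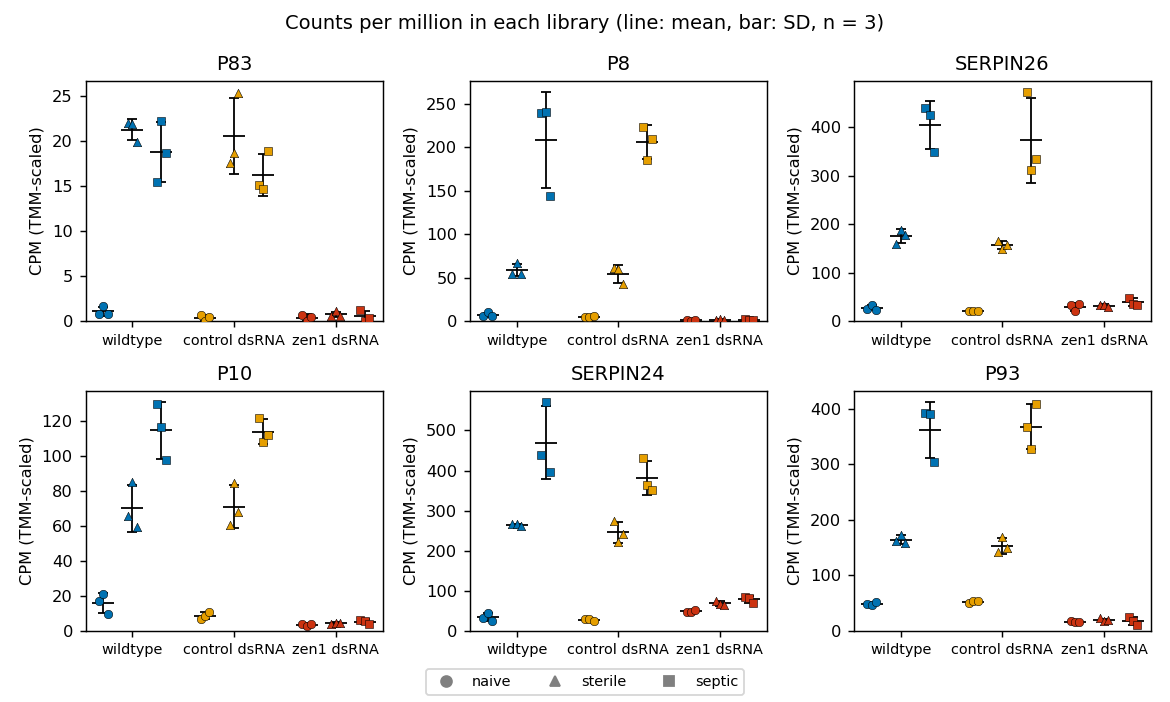
Counts per 1e6 reads (CPM) on a linear axis for P83, P8, SERPIN26, P10, SERPIN24 and P93 in every library, with the mean and SD of the 3 libraries of each group. P8 reaches 206 CPM in septic control and 1.77 CPM in septic zen1 eggs.

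Proteases and serpins differed as groups in this test. Of 38 proteases 9 had a lower and 1 a higher response in zen1 than in control eggs (17 and 1 adjusted over the list alone; camera adjusted p = 2.82e-14, and 5.84e-07 with an estimated correlation). Of 20 serpins 8 had a lower and none a higher response (9 and 0 adjusted over the list alone; adjusted p = 2.68e-12, and 0.000129 with an estimated correlation). Chemosensory receptors and binding proteins moved down as a list with no called member (adjusted p = 0.0184, and 0.0232 with an estimated correlation). No gene of the Toll pathway or of the heat shock list was called. The protease P13 (0.55, adjusted p = 0.0309) and CYP4H10 (1.47 ± 0.391, adjusted p = 0.0411) were the called genes with a symbol that had a higher response. P13 lost its call without any of 8 of the 12 libraries, and CYP4H10 without any of 9, with adjusted p up to 0.125 and 0.135. In all 220 genes differed, 37 with a higher and 183 with a lower response in zen1 eggs (263 with the block). Of the 410 genes at least 2-fold higher in septic control eggs, 365 were called higher in wildtype eggs, with a median log2 fold change of 1.97, and 100 in zen1 eggs, with a median of 0.594 against 1.98 in control eggs. Of the 152 genes at least 2-fold lower in septic control eggs, 88 were called lower in wildtype and 32 in zen1 eggs, with medians of -1.05 and -0.70 against -1.26 in control eggs, and 128 and 126 kept their sign.

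**Figure D4:**
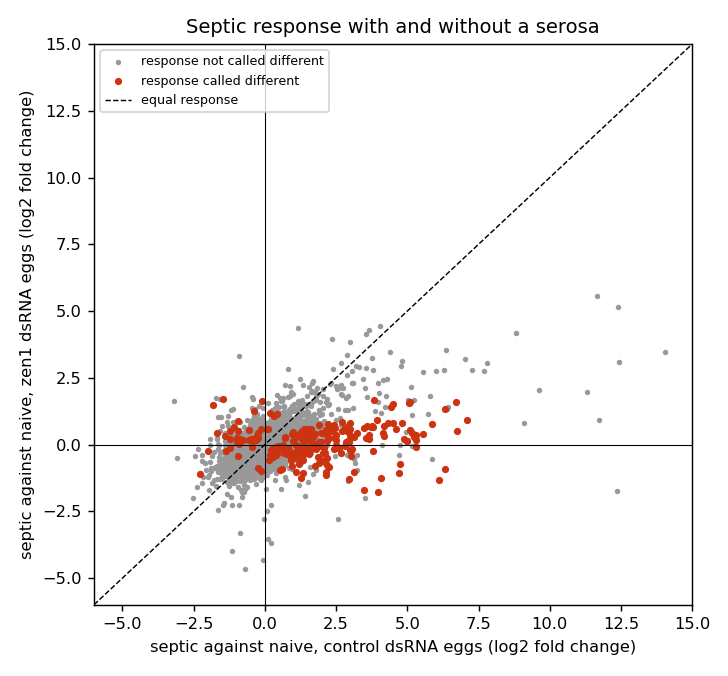
Log2 fold change after a septic prick in control eggs (x axis) and zen1 eggs (y axis) for each gene, with the 220 genes whose response differed in red and the dashed line at equal response. Most of the red points, 183 of 220, lie below the line.

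Against wildtype eggs the response of zen1 eggs differed for 246 genes, 57 with a higher and 189 with a lower response (296 with the block). P8 differed by -4.55, SERPIN26 by -3.62, SERPIN24 by -3.20, MMP1 by -3.15, GNBP3 by -2.38 and IMD by -1.89. Proteases (11 lower, 1 higher of 38; 17 and 1 adjusted over the list alone; camera adjusted p = 1.81e-10) and serpins (8 lower, none higher of 20; 9 and 1 adjusted over the list alone; 1.62e-10) kept their calls with an estimated correlation. The lists for the JNK pathway and wounding (0.0301), nervous system (0.0019), cell cycle (0.0328) and chemosensory receptors and binding proteins (0.0328) lost theirs, with adjusted p = 0.0914, 0.428, 0.428 and 0.0631 with an estimated correlation. The count was 453 without wildtype naive 3. Between control and wildtype eggs, which both have a serosa, edgeR called 0 genes with a different response, with 863 at an unadjusted p under 0.05; the block gave 0, DESeq2 called 1, and the edgeR count was 208 without wildtype naive 3. Neuronal and cell cycle lists were called there (9.02e-06 and 0.00821), with adjusted p = 0.517 for both with an estimated correlation.

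The response to the wound alone also differed between zen1 and control eggs. SERPIN26 went from 29.3 to 31.8 ± 2.65 CPM in zen1 against 20.6 to 157 ± 9.06 CPM in control eggs (difference in log2 response -2.89 ± 0.253, adjusted p = 1.77e-08). SERPIN24 differed by -2.71, MMP1 by -2.27 and GNBP3 by -2.13. P83 differed by -4.92 and P8 by -3.16, calls that were lost without zen1 naive 1 (adjusted p = 0.12 and 0.0537) or zen1 naive 3 (0.0906 and 0.227). Of 38 proteases 10 had a lower response and none a higher one (13 and 0 adjusted over the list alone; camera adjusted p = 1.71e-11, and 3.6e-06 with an estimated correlation). Among 20 serpins 8 were lower and none higher (10 and 0 adjusted over the list alone; adjusted p = 2.04e-13, and 6.33e-05 with an estimated correlation). Chemosensory receptors and binding proteins (0.00249) kept their call, while homologs and cytochrome P450 genes (0.0404 each) had adjusted p = 0.0522 and 0.317 with an estimated correlation. The 175 called genes, 33 with a higher and 142 with a lower response, numbered 205 with the block and 114 without zen1 naive 3.

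**Figure D5:**
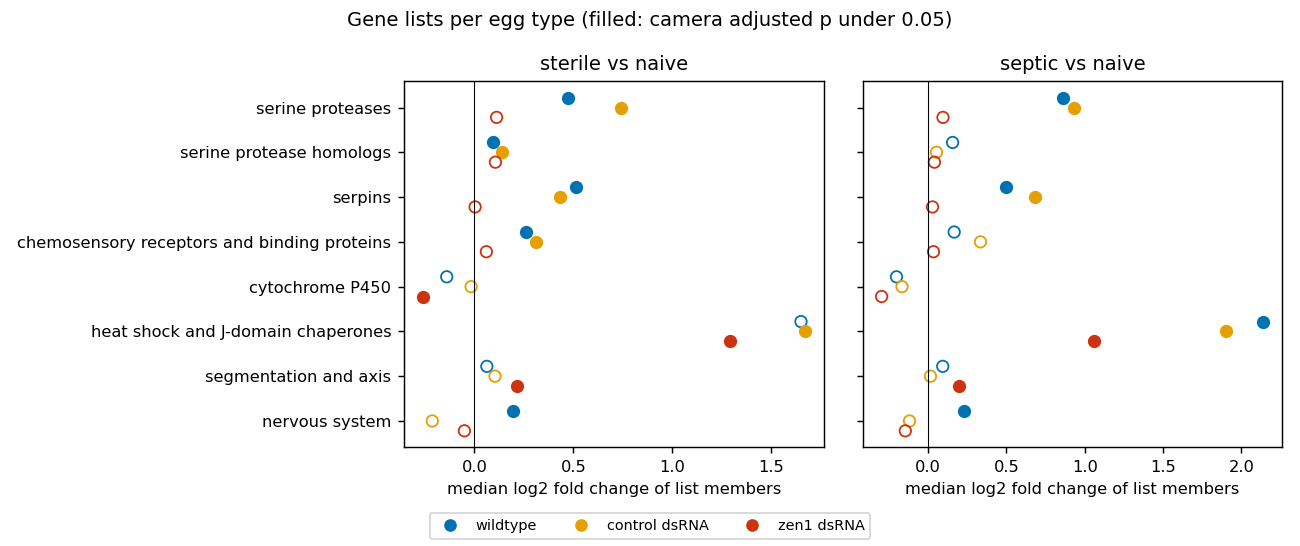
Median log2 fold change of 8 gene lists (y axis) after a sterile or septic prick in each egg type, with filled symbols for camera adjusted p under 0.05. Serine proteases and serpins are filled in wildtype and control eggs and open in zen1 eggs.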

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

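The thinning of reads, the ratio of reads between egg types, the zen1 against control test of the septic against sterile contrast, the tests of single naive libraries, the count of genes already high before the prick and the splits of balanced groups were chosen only after the results they address had been seen. The results on responses were picked out because the effect of a prick differed between egg types in a test of that difference; the difference between naive control and wildtype eggs was picked out because its count of 423 went to between 1 and 1195 when 1 of its 6 libraries was left out.

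The septic response differed between zen1 and control eggs for 220 genes, with P8 at -4.92, SERPIN26 at -3.86, P10 at -3.29, SERPIN24 at -3.15, P93 at -2.88, MMP1 at -2.65, SERPIN27 at -2.58 and GNBP3 at -2.50. HR38 was at -2.40 (-2.07 and adjusted p = 0.0678 without zen1 naive 3) and P83 at -5.11 (-4.63 and 0.0973 without zen1 naive 1, -5.19 and 0.0678 without zen1 naive 3). The higher responses of CYP4H10 (1.47) and P13 (0.55) depended on single libraries: among the fits that leave out 1 library, CYP4H10 kept its call only without control naive 3, zen1 septic 2 or zen1 septic 3, and P13 only without control naive 1, control septic 2, zen1 naive 1 or zen1 septic 2. Elsewhere their adjusted p reached 0.135 and 0.125.

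Between zen1 and wildtype eggs 246 genes differed, with P8 at -4.55 and CYP4H10 at 1.64. H70 was at -7.50 (-4.21 and adjusted p = 0.988 without zen1 naive 3) and P83 at -4.09 (adjusted p = 0.231, 0.137 and 0.0743 without zen1 naive 1, zen1 naive 3 and zen1 septic 3). ML1 was at 1.05 and lost its call without wildtype naive 2 (adjusted p = 0.0753), wildtype septic 1 (0.0647), zen1 naive 1 (0.0606), zen1 naive 2 (0.0505) or zen1 septic 3 (0.127). H3 was at 0.846 and lost its call without wildtype naive 1 (0.0615), wildtype septic 1 or 2 (0.0751, 0.0594), zen1 naive 1 or 3 (0.0661, 0.1) or zen1 septic 3 (0.22). The sterile response differed between zen1 and control eggs for 175 genes, with SERPIN26 at -2.89, P83 at -4.92 and P8 at -3.16; the last pair lost their calls without zen1 naive 1 (adjusted p = 0.12 and 0.0537) or zen1 naive 3 (0.0906 and 0.227).

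The first pattern weighed is the weaker septic response of zen1 eggs. A high level before the prick is argued against for these genes as a set, since their naive zen1 level was a median 0.217 of the control septic level, but it stays open for 38 of the 181 that had reached 0.5 of it or more; of all 181, 25 were called above and 46 below the naive control level in naive zen1 eggs. Injection of dsRNA as such is argued against: over the 189 genes with a lower response than in wildtype eggs, the control minus wildtype difference was 0.042 of the zen1 minus wildtype difference. With all 12 libraries thinned to 2.36 M reads, 117 genes were still called lower and 22 higher. At 1 equal depth, lower responses thus still outnumbered higher ones. Of the 183 genes called lower at full depth, a share of 0.634 stayed called with fewer reads, between the bounds first set. The comparison of lower with higher calls was added after that share was seen. The median difference of the 183 genes was -1.97 against -2.01 at full depth. Neither these counts nor this median can decide whether a difference in depth played a part, because thinning leaves the expected ratio between groups unchanged. The loss of the serosa, and any other change in development after the zen1 dsRNA, remain open as hypotheses that these eggs alone cannot separate.

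The second pattern is that bacteria added 2 called genes to the sterile prick in zen1 eggs. Lower depth is argued against, as the zen1 libraries held 1.13 times the reads of the control libraries after a septic and 1.18 times after a sterile prick. The spread was larger in septic zen1 eggs (median SD of log2 CPM 0.174 against 0.134 to 0.152 in the other groups), but as the whole cause it is argued against: over the 155 genes called in wildtype eggs, taken in the direction of that call, the median change was 0.00501 in zen1 and 0.859 in control eggs, a ratio of 0.00584, although for 37 of them the zen1 interval held the control value. A test of the difference between the contrasts called 32 genes, 9 higher and 23 lower, with REL at -1.07 (adjusted p = 0.00036), which is what fewer bacterial responders without a serosa would give. That explanation may hold, yet the same samples raised and tested it, and how many bacteria reached each egg is not recorded.

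The third pattern is the difference between naive control and wildtype eggs, where the count of 423 was 2, 1 and 1195 without wildtype naive 1, 2 and 3 and 2, 6 and 640 without control naive 1, 2 and 3. The median difference over the called genes kept at least a share of 0.789 without any 1 wildtype naive library. The same libraries had chosen these genes, which favours genes on which they agree. This share therefore cannot decide whether a single deviating wildtype naive library was the cause. The fold changes correlated across genes with the main deviation between replicates of the 7 other groups at 0.427, and genes are not independent replicates. That deviation held 18.7% of the variation between replicates of those groups, and the labels do not tie it to age. Nor was it tested against replicate number, although the count fell without replicate 1 or 2 of either type and rose without replicate 3. A difference in age or state that varies between replicates could produce the third pattern. Injection of the mothers cannot be told apart from this, because the share of called genes keeping their sign was 0.761 in septic eggs (322 of 423), between the bounds set, and 0.83 in sterile eggs (351 of 423), above the upper one. Yet the median change there was 0.144 and 0.141 of that in naive eggs, and edgeR called 0 genes in either (334 and 253 at an unadjusted p under 0.05), so a lasting effect of dsRNA and a difference in egg age both stay open.

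Other splits of the samples were counted for every comparison. For each comparison of 3 libraries with 3, there are 10 splits, too few for a share under 0.05, and the real split alone (1 of 10) gave as many genes. The highest count in another split was 3, 1 and 1 for septic against naive in wildtype, control and zen1 eggs, 0, 0 and 1 for sterile against naive, 0, 4 and 1 for septic against sterile, 1 for zen1 against control, 13 for zen1 against wildtype and 14 for control against wildtype. For the differences in response, 100 splits exchanged egg types within treatments. As many genes as with the real labels came from 12 of them for the septic response of zen1 against control (real 220, highest other 1163), 12 against wildtype (246, 1135) and 13 for the sterile response (175, 1237), so chance was not excluded by this count. Splits with counts that high point to a structure of the samples, as they exchange the egg types in 1 treatment and turn the difference between egg types into a difference in response. For the septic response of control against wildtype the count is void, as every split reaches the real count of 0. Among the 29 splits that exchange egg types equally in both treatments, the real one alone reached its count in the tests of zen1 eggs, and the highest others were 0, 75 and 0 for the septic response against control, that against wildtype and the sterile response. The other balanced splits put both egg types into the same group, which widens the spread within groups. Their low counts therefore do not favour the real labels.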

How the results depend on the processing

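Unique exon reads were added as an alternative after the files were seen, and all other settings were planned; single libraries left out were treated as varying like the remaining ones. No alternative reversed a result, and the median log2 fold change of all genes lay between -0.018 and 0.014 in every comparison with RLE scaling. With an adjusted p under 0.01 and at least a 2-fold change, fewer genes pass by construction: septic against naive 504, 447 and 99 in wildtype, control and zen1 eggs, sterile against naive 297, 274 and 218, septic against sterile 62, 61 and 0, zen1 against control 256, zen1 against wildtype 276, control against wildtype 6, the septic response of zen1 against control 123 and against wildtype 150, and the sterile response 86. Fitting only the compared groups leaves fewer samples to estimate the spread, and counts moved both ways. It gave 1167 genes for septic wildtype, 370 for septic zen1, 0 for septic against sterile zen1, 386 for zen1 against wildtype and 0 for control against wildtype. By contrast, septic control had 1571 genes and septic against sterile control 166. Sterile zen1 had 1364, against 1391 in the main fit. ZEN in naive eggs moved to -3.38 (adjusted p = 0.0499). For control against wildtype in the septic response, no filter and DESeq2 gave 1 gene each; DESeq2 put ZEN in septic eggs at -3.57 (adjusted p = 0.0786). The cause was not tested.

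Lists called with an estimated correlation numbered 2 for septic wildtype, 0 for septic and sterile zen1, and 0 and 1 for septic against sterile in wildtype and control. They numbered 0 for control against wildtype naive, 2 for the septic response of zen1 against wildtype, 0 for that of control against wildtype and 3 for the sterile response. With the replicate number as a block 1 list was called in septic zen1 eggs. Libraries sharing a number were more alike: their deviations correlated at -0.30 to 0.42 (median 0.081, 48 of 108 pairs over 0.1), against a median of -0.036 and 28 of 216 pairs for different numbers, and 19 of 27 libraries correlated best with their own number. The counts of called genes with the block stayed within 1.5 times of those without it.

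Without single libraries the counts ran from 512 to 1005 for sterile wildtype, 1 to 1195 for control against wildtype, 190 to 453 and 0 to 208 for the septic responses of zen1 and control against wildtype, 87 to 248 for septic against sterile wildtype, 114 to 159 for the sterile response, 267 to 1045 for septic zen1, 831 to 1241 for sterile zen1 and 0 to 2 for septic against sterile zen1. ZEN in naive, sterile and septic eggs ran from -5.352 to -2.992, -3.317 to -1.562 and -3.906 to -2.99 against control and from -4.551 to -2.048, -2.432 to -0.3192 and -3.248 to -2.142 against wildtype. Counts of the other comparisons stayed within 1.5 times, such as 1034 to 1363 for septic control, 168 to 221 for the septic response of zen1 against control and 469 to 567 for zen1 against control naive. Of 577 values of named genes none reversed, and a call was lost for 6 with RLE, 19 with no filter, 2 with the block, 24 with DESeq2, 7 of 575 with unique reads, 102 of 566 with only the compared groups and 715 of 3936 without a library. Depth limits ZEN, H70 and SPZ-LIKE in zen1 eggs, where levels near 0 leave wide standard errors.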

Other observations

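The genes lower in naive zen1 eggs and the levels in septic eggs were looked at only after the other results had been seen. The 257 genes at least 2-fold lower in naive zen1 than in naive control eggs made up 5.56% of the reads of naive wildtype eggs. In wildtype eggs they went both ways after a prick. The wildtype libraries were not compared in choosing these genes, but they entered the count filter and the shared estimate of the spread. Chance here is the share called over all 9415 genes, not matched for level. After the septic prick 70 of them rose, where chance gives 28.2, and 98 fell, where chance gives 21. After the sterile prick 70 rose and 65 fell, against 13.1 and 8.11 by chance. A symbol is known for 38 of them.

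Levels in septic eggs differed between zen1 and control eggs for 831 genes, 231 higher and 600 lower. P8 had 1.77 CPM in zen1 and 206 CPM in control eggs (log2 difference -6.89), and IMD and REL were at -2.03 and -0.66. The heat shock gene HSP68B at 6605773 was at 24.1 CPM in septic zen1 and 24.7 CPM in septic control eggs (-0.09, adjusted p = 0.954).

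Genes that rose with the septic prick often lay side by side. Among the 387 placed genes at least 2-fold higher in septic wildtype eggs, 53 pairs were direct neighbours among the 8650 tested genes with a position. Shuffling the calls 10000 times gave a median of 17 pairs and at most 36, a one-sided permutation p of 1e-04, the smallest these shuffles can give, and the count was 51 pairs with unique reads. On linkage group 2, P10 (12928377 to 12931501), P9 (12931382 to 12933271) and P8 (12933846 to 12935653) rose by 2.94, 4.73 and 4.92, and the first pair overlap. A hypothesis is that tandem copies of immune genes respond together; shared reads within copies or overlaps may add pairs, and sequence similarity was not compared.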
